A study of Mus musculus with 5 samples.

How the data were processed

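Single-cell RNA sequencing was done on live CD45-positive cells sorted from enzyme-digested B16-F10 tumors that were taken on day 11 after 500000 tumor cells had been injected under the skin, per the labels' protocols. About 16000 cells were loaded per library with a 5' droplet kit and sequenced on a NovaSeq instrument. Each of the 5 libraries is a treatment of its own, namely PBS, anti-PD1, IL15 superagonist, combination and fusion, taken from the treatment given in the labels. How many mice contributed to a library is not given in the sources used here.

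The deposited files hold UMI counts per gene and cell barcode as whole numbers, made with Cell Ranger 2.1.1 on genome build mm10, per the submitters' processing notes. The barcode filter, the annotation release and the handling of reads shared between similar genes are not given in the sources used here. Each file lists 28692 genes with symbols and Ensembl identifiers, of which 67 symbols occur more than once and were kept apart by identifier. The lowest UMI count per barcode differed, at 1751 in PBS, 2119 in anti-PD1, 1981 in IL15 superagonist, 2312 in combination and 2671 in fusion. Coordinates were taken by identifier from GENCODE release 21 for mouse on mm10. No label or header gives a sequencing batch or date.

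Cells with at least 200 genes and at most 10% of UMIs from mitochondrial genes were kept. The mitochondrial limit removed 70, 58, 92, 84 and 90 barcodes in the order above, and the gene limit 0. Scrublet marked 0, 0, 1, 0 and 0 cells as doublets, so it had not worked, and the fallback fixed in advance was used. It removed cells with markers of 2 lineages, each with at least 2 genes and 3 UMIs, which were 229, 372, 189, 327 and 169 cells, or 3.85%, 5.10%, 2.83%, 3.85% and 1.95%. Doublets within a lineage, such as 2 T cells, remain.

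Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 20 neighbours and Leiden clustering at resolution 1 were computed over all libraries with scanpy 1.11.5, igraph 0.11.9 and leidenalg 0.10.2, with no integration across libraries. T and NK clusters were clustered again on their own. Genes of the fixed lists that are not class markers, mitochondrial and ribosomal genes, and V, D and J segments were left out of the variable genes, so that of the list genes only class markers can define clusters. Clusters were named from markers of 20 classes, with at least 3 markers detected in at least 20% of the cluster's cells. Clusters in which most of the markers particular to the best class were not detected stayed unnamed, which left T0, T13 and T15. The detection limit for markers was set after the data were seen. Cluster T3 of the CD8 T-like class was led by Cd8a, Cxcr6, Pdcd1, Tox and Lag3, T4 by Gzmk, Themis and Lat, T7 by Dapl1, S1pr1, Lef1 and Tcf7, T9 by Ube2c and Dut, and T11 by Ccl1, Ifng and Xcl1. T2, T5 and T6 were led by Gzmf and Serpine2, T5 and T6 also by Rrm2. The NK-like clusters T1 and T8 were led by Klra4, Klra8 and Ncr1, T1 also by Gzma. Cluster A4 of the macrophage-like class was led by Pf4, Ccl8 and C1qc.

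UMIs of a class were summed per library and given as CPM of all its UMIs, with exact Poisson 95% intervals. The ratio of libraries has an exact conditional interval from the binomial distribution, and shares of cells have exact Clopper-Pearson intervals. Classes with at least 100 cells in both libraries were compared, which left CD4 T-like cells for 3 and Treg-like cells for 3 of the 7 comparisons. A count of 0 was set to a floor of 3 counts of the class for a fold. No test was made between treatments, since each has 1 library. Comparisons were anti-PD1, IL15 superagonist, combination and fusion with PBS, fusion with combination, and combination with anti-PD1 and with IL15 superagonist.

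The gene lists, of which there are 21, were fixed in advance: cell cycle, cytotoxic effector, inhibitory receptor and exhaustion, stem-like and memory, IL-2 and IL-15 receptor with STAT5 targets, type I interferon response, interferon-gamma response, chemokine and chemokine receptor, NK-cell receptor, costimulatory receptor, glycolysis, oxidative phosphorylation, immediate early and heat shock, Treg function, MHC class II and antigen presentation, alternatively activated and suppressive myeloid, inflammatory myeloid, tumor-cell transcripts, hemoglobin transcripts, sex-linked transcripts and housekeeping. A list's value is the median log2 ratio of members with at least 20 UMIs over both libraries, after adding 0.5 to each count, for lists with at least 4 such members. Its percentile was taken among 10000 random lists of the same size matched in 20 bins of mean expression. A list was called where its percentile was outside 2.5 to 97.5. To count as called when settings were changed, its median also had to lie at least 1.5-fold from equal levels.

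Genes were named by a fixed rule. For CD8 T-like cells these are the 8 higher and 8 lower genes per comparison with the largest counting bound nearest to equal levels, among genes with at least 50 UMIs over both libraries. For CD4 T-like, Treg-like, NK-like, macrophage-like and monocyte-like cells they are the 4 higher and 4 lower. Mitochondrial, ribosomal, receptor segment, hemoglobin, sex-linked and predicted genes were left out. Also named are 2 to 4 list members with the largest bound and, in any case, Cd8a, Cd4, Foxp3, Ncr1, C1qa, Mki67, Gzmb, Ifng, Pdcd1, Tcf7, Havcr2 and Il2rb. A list member that met this rule is not reported here. The treatment groups, the comparisons, the lists, the markers, the naming rule and the alternative settings other than the added ones were chosen before the data were examined.

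Shares of cells with a UMI were taken after thinning each cell to 2000 UMIs. A beta-chain V segment was assigned to CD8 T-like cells with at least 2 Trbv UMIs of which at least 80% came from 1 segment. Genes apart in a library across 6 classes, a check added after the data were seen, needed at least 200 UMIs in each class over all libraries. The alternatives covered cell filters, doublets, clustering resolution, classing by marker UMIs, scaling, depth, list filters and denominators, 15 settings in all. Of these a common minimum of 2671 UMIs, the share among cells other than CD8 T-like cells and anti-PD1 as the reference were added after seeing the data.

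The steps for ratios and lists were tested on simulated data for CD8 T-like cells of fusion against PBS, with 11019 genes of which 200 were changed. Counting intervals excluded equal levels for 77.6%, 94.0% and 97.0% of genes changed 1.5-fold, 2-fold and 4-fold, and for 3.97% of unchanged genes. They held the true ratio for 96.0% of genes, which checks counting error only. A list of genes raised 2-fold lay at percentile 100, and 0 of 20 lists of unchanged genes lay outside the limits. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.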

Results

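The study asked how an engineered form of interleukin 15 fused to an antibody against PD-1 acts on T cells inside tumors, compared with its parts given alone or as a mixture. B16-F10 cells, a line of mouse melanoma, had been placed under the skin of mice at 500000 cells per animal, and tumors were taken 11 days later. Live CD45-positive cells, the white blood cells of the tumor, were sorted for droplet-based single-cell RNA sequencing from the 5' end of transcripts. There were 5 libraries, 1 for each treatment: saline (PBS), an antibody against PD-1 (anti-PD1), an IL15 superagonist, the IL15 superagonist together with the antibody (combination) and the anti-PD1-IL15 protein fusion (fusion). For the combination the title of the library names the superagonist, whereas its treatment tag names IL15 only, and the title was followed. Interleukin 15 is a cytokine that acts on CD8 T cells and natural killer (NK) cells through the receptor chains Il2rb and Il2rg, and PD-1, encoded by Pdcd1, is an inhibitory receptor of activated T cells.

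The PBS library held 6015 barcodes with 32832856 unique molecular identifiers (UMIs), the anti-PD1 library 7350 with 50251271, the IL15 superagonist library 6779 with 39479966, the combination library 8577 with 55152013 and the fusion library 8747 with 81565425. Median UMIs per barcode were 4498, 5667, 4279, 4933 and 7851, in that order. After filters 35788 cells were used: 5716, 6920, 6498, 8166 and 8488. With 1 library per treatment there is no replicate check and no test between treatments, so each value describes these libraries. Levels are summed UMIs of a class as CPM, counts scaled to the total of the class. Values in parentheses after a fold are its exact conditional 95% interval, and those after a share its exact Clopper-Pearson 95% interval. Both cover counting error only. Values in parentheses after a list's median log2 ratio are the 95% interval of the median over its members, and its percentile is its rank among 10000 random lists matched on expression. Members called higher or lower are those whose counting interval excludes equal levels. The labels place treatment after the tumors were taken, so the interval between treatment and sampling is not given.

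Cells were grouped into classes by clustering and fixed markers. CD8 T-like cells made up 17.8% (16.8% to 18.8%) of the PBS library, 16.5% (15.7% to 17.4%) of anti-PD1, 29.7% (28.6% to 30.8%) of IL15 superagonist, 38.4% (37.3% to 39.4%) of combination and 77.7% (76.7% to 78.5%) of fusion. NK-like cells were 6.91%, 9.16%, 20.7%, 13.5% and 2.97% in the same order. Regulatory T (Treg)-like cells, which carry the transcription factor Foxp3, were 3.80%, 2.90%, 1.17%, 2.46% and 0.295%. The ratio of CD8 T-like to Treg-like cells was 4.70 (4.05 to 5.46) in PBS, 5.70 (4.90 to 6.65) in anti-PD1, 25.4 (20.2 to 32.3) in IL15 superagonist, 15.6 (13.5 to 18.1) in combination and 264 (178 to 408) in fusion. Monocyte-like cells were 21.2%, 33.8%, 12.9%, 16.9% and 5.23%, and macrophage-like cells, marked by complement C1q genes, were 22.6%, 18.0%, 9.96%, 6.97% and 3.11%. A cluster of Cd3-positive cells that could not be named, T0, led by Klra6, Klra1 and Pde2a, held 4.43%, 4.71%, 13.7%, 11.0% and 6.96%. Clusters T13 and T15, which could not be named either, held 1.73%, 1.08%, 3.39%, 2.66% and 1.87%. B-like cells were 2.34% of PBS and 0.0353% of fusion cells, and dendritic cells of type 2 (cDC2-like) 8.66% and 0.766%. Shares add up to a whole, so the CD8 T-like share of the fusion library lowers all its other shares. The sort for CD45, the number of cells loaded and the lowest UMI count per barcode, from 1751 in PBS to 2671 in fusion, can also set shares.

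**Figure D1:**
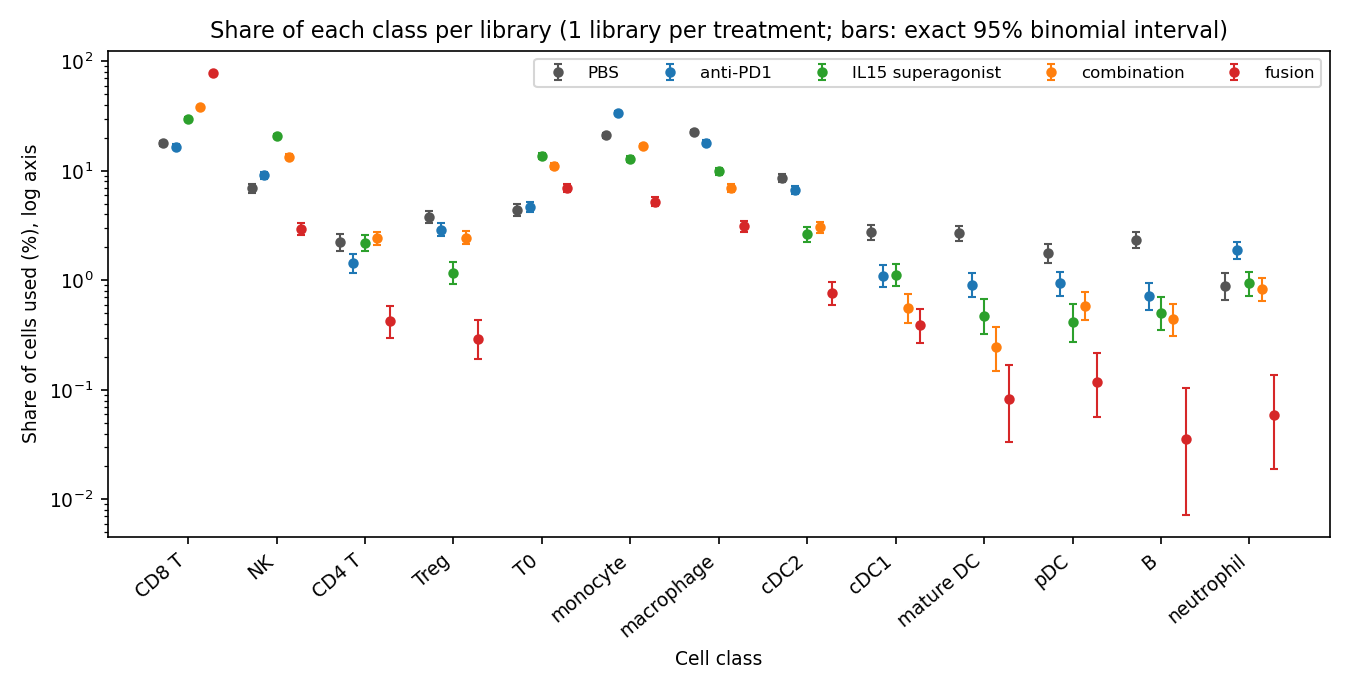
Share of each cell class per library in percent, on a log axis, with a point per library and exact 95% binomial intervals as bars. CD8 T-like cells range from 16.5% in anti-PD1 to 77.7% in fusion, and Treg-like cells from 0.295% in fusion to 3.80% in PBS.

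The PBS library stood apart from the others in a way that crossed cell classes. UMIs of beta-chain V segments (Trbv) per UMI of the beta-chain constant regions (Trbc) in CD8 T-like cells came to 0.274 (0.258 to 0.290) in PBS, against 1.41, 2.95, 2.37 and 3.56 in anti-PD1, IL15 superagonist, combination and fusion. Of 4208 genes compared in 6 classes, 15 lay apart from all other libraries by over 0.5 on the log2 scale in the same direction in every class in PBS, and 0, 0, 0 and 1 did in the others. These genes were chosen after their values were seen. Higher in PBS were Gm10076, Sod1, Strn3, Arfgef1, Hnrnpa0 and Rpl13-ps3, and lower were Aldoa, Eno1b, Hmga1, Nutf2, Cops6, Eif5a, Gzmb, Atp6v0c and Asna1. The glycolytic gene Aldoa is among them, which bears on each comparison with PBS. The serine protease gene Gzmb is no separate sign in myeloid classes, which should lack it.

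**Figure D2:**
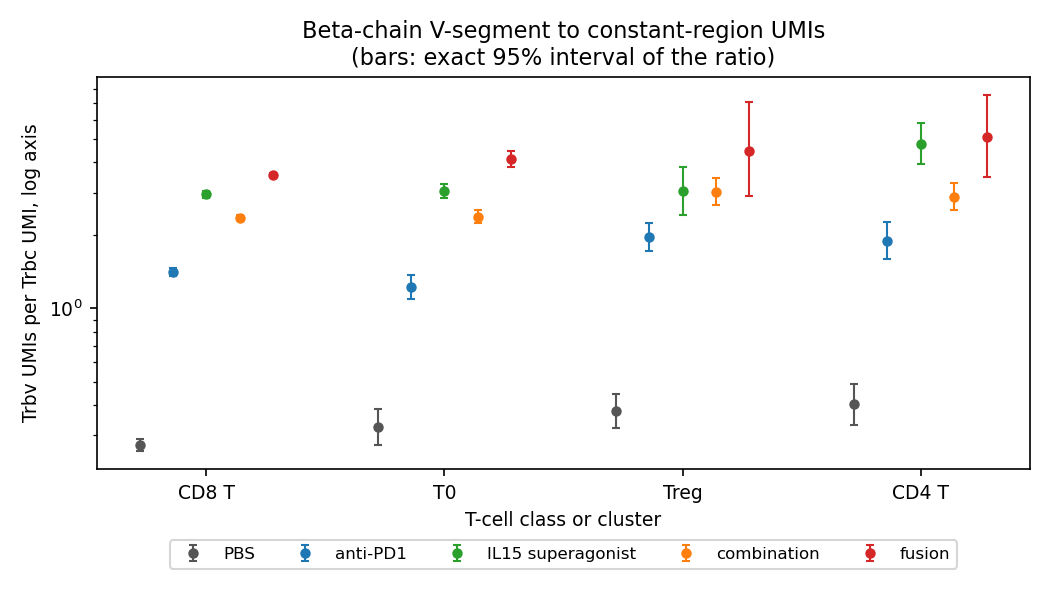
Trbv UMIs per Trbc UMI in 3 T-cell classes and cluster T0, on a log axis, with a point per library and exact 95% intervals of the ratio as bars. PBS lies lowest in each, at 0.274 in CD8 T-like cells against 1.41 to 3.56 in the other libraries.

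The comparison of anti-PD1 with PBS asks what blocking PD-1 alone does. CD8 T-like cells of anti-PD1 had higher cytotoxic and interferon-response genes than those of PBS. Their share of all cells was 16.5% against 17.8%, with overlapping intervals, while monocyte-like cells were 33.8% against 21.2%. Of the 8 genes that were higher by the fixed rule, Ifitm1, which encodes an interferon-induced transmembrane protein that restricts virus entry, stood first at 61.5 against 2.74 CPM, 22.5-fold higher (13.9 to 38.9). The related Ifitm2 was 5.30-fold higher (3.87 to 7.42), Hspa1a, the inducible heat shock protein of the Hsp70 family, 6.25-fold higher (4.82 to 8.23), and the granzyme gene Gzma 3.65-fold higher (3.28 to 4.07). H2-Eb1 and H2-Aa, which encode MHC class II chains, were 5.12-fold higher (3.87 to 6.88) and 5.00-fold higher (3.85 to 6.58). Adnp was 6.96-fold higher (3.50 to 15.7) and Ccl1, a chemokine that binds Ccr8, 4.08-fold higher (3.41 to 4.90). The 8 lower genes were Xlr, Ctnnd2, Slco2a1, Arnt2, Ndnf, Btg3, Mrc2 and Dscam, from 3.78-fold to 13.1-fold lower, and each lay at 28.6 CPM or less in PBS. With doublets kept Ifitm1 was 3.11-fold higher, Ifitm2 1.69-fold, Hspa1a 1.39-fold, H2-Eb1 2.49-fold and H2-Aa 2.27-fold. These sizes rest on doublet removal.

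Of 17 cytotoxic effector genes 15 were higher and 0 lower, with a median log2 ratio of 1.16 (0.52 to 1.45) at percentile 100. IL15 superagonist against anti-PD1 had a median of -0.073, so this result rests on the PBS library. Gzme was 93.2 against 28.2 CPM, 3.31-fold higher (2.81 to 3.92). Prf1, the perforin gene, was 428 against 156 CPM, 2.74-fold higher (2.55 to 2.95). Gzmb, low in all 6 classes compared in PBS, was 1931 against 680.5 CPM, 2.84-fold higher (2.74 to 2.94). The type I interferon response list had 16 of 21 members higher and a median of 0.68 (0.51 to 1.07), with Zbp1 2.18-fold higher (1.93 to 2.46) and Isg15 2.13-fold higher (1.90 to 2.38). For glycolysis 13 of 16 were higher and the median was 0.53 (0.30 to 0.92). Aldoa, also low in all 6 classes of PBS, was 2.28-fold higher (2.19 to 2.38). The MHC class II and antigen presentation list had 10 of 13 members higher and 0 lower, with a median of 0.38 (0.042 to 1.59). For the inflammatory myeloid list it was 6 of 10, with a median of 1.03 (0.25 to 1.30). RNA of other cells was not excluded for their members. Cell cycle genes split, 7 higher and 9 lower, around a median of -0.095 (-0.17 to 0.10). Inhibitory receptor genes had a median of 0.033 (-0.46 to 0.41), although Pdcd1 itself was 546 against 378 CPM, 1.45-fold higher (1.38 to 1.52). Among single genes fixed in advance, Ifng, the cytokine interferon gamma, was 250.4 against 102 CPM, 2.47-fold higher (2.25 to 2.70), the inhibitory receptor gene Havcr2 1.25-fold higher (1.12 to 1.39), the stem-like marker Tcf7 1.40-fold higher (1.18 to 1.66), the receptor gene Il2rb 1.08-fold lower (1.04 to 1.13), and the class marker Cd8a 1.10-fold higher (1.06 to 1.14). Cluster T3 held 35.7% of CD8 T-like cells in anti-PD1 and 52.3% in PBS, and T4 15.5% and 9.32%.

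Gzmd and Gzme were higher in NK-like cells, and Nos2 in both myeloid classes. In NK-like cells, mostly of cluster T8 in both libraries (77.3% and 95.7%), the granzyme genes Gzmd and Gzme were 32.7-fold higher (18.6 to 63.5) and 11.4-fold higher (5.41 to 28.8), Gzmg, with 0 UMIs in PBS, at least 102-fold higher than the level of 3 counts, and Ccl4, a chemokine, 5.28-fold higher (4.68 to 5.97). Nr4a3, Pmepa1, Hes1 and Hmbox1 were lower there, from 2.73-fold to 3.59-fold. Treg-like cells had Ccl3 5.52-fold higher (3.84 to 8.16), with Ccl4, Gzma and Prf1 also higher, and Il1rl1, the receptor for interleukin 33, 5.65-fold lower (3.95 to 8.30), with Ctsh, Polr2l and Nr4a3 also lower. Foxp3 was 1.12-fold higher (0.972 to 1.29) in them. In macrophage-like cells Nos2, the inducible nitric oxide synthase, was 151 against 20.6 CPM, 7.34-fold higher (6.23 to 8.70), with Hspb1, Upp1 and Inhba also higher and Pmepa1, Ccdc122, Trf and Timp2 lower. Cluster A11, led by Arg1, Mmp12, Hspa1a and Nos2, held 43.1% of macrophage-like cells in anti-PD1 and 14.5% in PBS, so the makeup of the class differed. Monocyte-like cells had Nos2 at 114 against 9.56 CPM, 11.9-fold higher (9.08 to 15.9), Ccl8 8.29-fold higher (6.79 to 10.2), Upp1 6.43-fold higher (5.54 to 7.51) and Ifnb1, the interferon beta gene, with 0 UMIs in PBS, at least 8.85-fold higher than the level of 3 counts, and lower Wnt11, Dmkn, Lyz1 and Trf. The interferon-gamma response list was higher in 19 of 20 members in monocyte-like cells, with a median of 0.73 (0.59 to 0.96). At double the clustering resolution Gzmd in NK-like cells was 1.56-fold and Ccl8 in monocyte-like cells 1.02-fold higher, so neither size is stable.

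The IL15 superagonist was compared with PBS to show the effect of the cytokine alone. Its library had more NK-like cells, 20.7% against 6.91%, and fewer Treg-like cells, 3.25-fold lower. Among T and NK cells these were 29.3% against 18.7% and 1.65% against 10.3%. CD8 T-like cells were 29.7% against 17.8% of all cells but 41.9% against 48.3% of T and NK cells, so their direction turns with the denominator. These CD8 T-like cells had higher stem-like genes and lower cell cycle genes. Stem-like and memory genes were higher in 14 of 14 members, with a median of 1.41 (1.18 to 2.04) at percentile 100. Examples were Ly6c2 at 4.37-fold higher (4.13 to 4.63), Lef1, a transcription factor partner of Tcf7, at 4.16-fold higher (3.49 to 5.00) and S1pr1, which lets cells leave tissue, at 3.90-fold higher (3.29 to 4.66). Tcf7 was 87.0 against 33.6 CPM, 2.59-fold higher (2.23 to 3.02). Of 33 cell cycle genes 31 were lower and 0 higher, with a median of -0.82 (-1.02 to -0.66), and Mki67, a marker of dividing cells, was 72.2 against 161 CPM, 2.23-fold lower (2.03 to 2.45). Ccne2, Rrm1 and Top2a were 3.29-fold lower (2.41 to 4.53), 2.66-fold lower (2.38 to 2.97) and 2.43-fold lower (2.25 to 2.62).

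By the fixed rule Ifitm1 was 107 against 2.74 CPM, 39.2-fold higher (24.4 to 67.6), Gzma 927 against 64.7 CPM, 14.3-fold higher (12.96 to 15.9), Ccl1 11.8-fold higher (10.0 to 14.1), Anxa1, which encodes annexin A1, 15.6-fold higher (8.79 to 30.4), Ifitm2 11.6-fold higher (8.62 to 16.0), Fcgrt, the neonatal Fc receptor, 16.0-fold higher (6.69 to 49.95) and Adnp 11.8-fold higher (6.09 to 26.2). Prss2, a trypsin gene, was 8.19 CPM against 0 UMIs in PBS, at least 17.0-fold higher than the level of 3 counts. Lower were Wnt11, Itgb8, Ltf, Arnt2, Mrc2, Xlr, Galnt18 and Tmprss6, from 6.10-fold to 26.8-fold. With doublets kept Ifitm1 was 4.04-fold, Ifitm2 1.29-fold, Anxa1 3.87-fold and Fcgrt 6.47-fold higher. The cytotoxic effector list had 16 of 17 members higher with a median of 0.99 (0.79 to 1.51), including Gzmb at 2.18-fold higher (2.104 to 2.25). Against anti-PD1 in place of PBS, a choice made after seeing the data, the cytotoxic effector list in CD8 T cells, IL15 superagonist vs PBS, had a median of -0.073. A rise with both treatments and a low level particular to PBS would each give this, and they are not told apart. NK-cell receptor genes had 17 of 20 members higher and 2 lower, with a median of 1.55 (0.87 to 2.12). For targets of the IL-2 and IL-15 receptor and STAT5 it was 0.66 (-0.070 to 1.06), with 11 higher and 4 lower, while Il2rb itself was 1.05-fold lower (1.01 to 1.09). The inhibitory receptor list had 6 higher and 12 lower around -0.35 (-0.80 to 0.40), with Pdcd1 1.51-fold higher (1.44 to 1.59) and Havcr2 1.39-fold lower (1.24 to 1.55). Ifng was 1.73-fold higher (1.58 to 1.89) and Cd8a 1.04-fold lower (1.00 to 1.08). Immediate early and heat shock genes, which respond to tissue digestion, had a median of 0.63 (-0.16 to 0.94). Without doublet removal the immediate early and heat shock (dissociation) list in CD8 T cells, IL15 superagonist vs PBS, fell on the other side of 0, at -0.078. Clusters T4 and T7 held 26.0% and 27.0% of these cells, against 9.32% and 10.0% in PBS, where T3 held 52.3% against 22.2%.

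NK-like cells of this library came to 96.6% from cluster T1, whereas those of PBS came to 95.7% from T8. Their granzyme genes were higher, Gzmf at 407 against 2.60 CPM, 156-fold higher (53.4 to 759), Gzmd at 53.5-fold higher (30.6 to 104), Gzme at 34.9-fold higher (16.9 to 87.1) and Gzmg at 351 CPM against 0 UMIs, at least 135-fold higher than the level of 3 counts. The T-cell genes Cd3g and Cd8b1, chosen after their values were seen, were also higher in this class, at 175 against 19.1 and 31.5 against 5.20 CPM. At double the clustering resolution Gzmf and Gzmg were 51.0-fold and 32.0-fold higher, and at equal depth Gzmf 33.7-fold. Ncr1, an activating receptor and marker of NK cells, was 331 against 166 CPM, 1.996-fold higher (1.72 to 2.33), and Tcf7 4.97-fold lower (3.99 to 6.18). Zbtb10, Hspa1b, Hspa1a and Cd83 were lower, from 7.39-fold to 12.2-fold. Members of the granzyme cluster are similar in sequence, and how reads shared among them were counted is not given. Levels of single members are therefore uncertain, and likewise for Klra, Ifitm and histone genes.

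CD4 T-like cells, 142 cells against 128, had Il5, a cytokine of type 2 immunity, at 660.5 against 77.7 CPM, 8.50-fold higher (5.89 to 12.7), Ifitm1 8.75-fold higher (4.81 to 17.4), Cebpb 6.86-fold higher (4.73 to 10.3) and Klf2 4.55-fold higher (3.43 to 6.11). The opioid precursor gene Penk was 12.2-fold lower (6.59 to 25.04), with Ccl1, Slc12a2 and Ptprs also lower and the class marker Cd4 1.52-fold lower (1.22 to 1.89). Rora, a marker of type 2 innate lymphoid cells, is among the leading genes of their cluster, and such cells were not excluded. Macrophage-like cells had higher cell cycle genes, 31 of 33 with a median of 1.01 (0.84 to 1.10), and lower type I interferon response genes, 18 of 22 with a median of -0.71 (-0.86 to -0.40). By the fixed rule Ifnb1, Hspb1, Gzma and Cxcl1 were higher there, Ifnb1 at 6.29-fold higher (4.21 to 9.67) and Gzma at 77.3 CPM, beside 16304 in NK-like cells of the library, and S100a9, Ly6c2, Ccl17 and Slfn4 lower, Ly6c2 at 6.37-fold lower (5.73 to 7.09). Monocyte-like cells also had lower type I interferon response genes, 20 of 22 with a median of -0.85 (-1.17 to -0.40). Slfn4, Cxcr4, Ramp3 and Rsad2 were lower in them, Slfn4 at 5.83-fold lower (4.77 to 7.17), and Gzmc, Kcna3, Mmp12 and Cxcl1 higher, Cxcl1 at 5.29-fold higher (4.597 to 6.11).

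The combination was compared with PBS to show the effect of both agents mixed. CD8 T-like cells were 38.4% against 17.8%, 2.15-fold higher, and 54.5% against 48.3% of T and NK cells. NK-like cells were 1.95-fold higher and Treg-like cells 1.54-fold lower, but of T and NK cells alone NK-like cells were 19.1% against 18.7% and Treg-like cells 3.50% against 10.3%. Among cells other than CD8 T-like cells the log2 ratio of the Treg-like share was -0.21 (-0.49 to 0.073). In CD8 T-like cells Ifitm1 was 116 against 2.74 CPM, 42.4-fold higher (26.5 to 73.0), Gzma 820.0 against 64.7 CPM, 12.7-fold higher (11.5 to 14.0), Ifitm2 10.1-fold higher (7.53 to 13.9) and Anxa1 12.7-fold higher (7.19 to 24.7). The integrin chain genes Itga1 and Itgax were 9.95-fold higher (5.50 to 20.1) and 7.82-fold higher (5.07 to 12.7), Adnp 9.19-fold higher (4.77 to 20.3), and the chemokine receptor gene Cxcr3 5.71-fold higher (4.56 to 7.24). Wnt11, Rln3, Xlr, Arnt2, Mrc2, Hist1h2ap, Galnt18 and Igfbp4 were lower, from 8.82-fold to 26.9-fold. With doublets kept Ifitm1 was 4.599-fold, Ifitm2 1.32-fold, Anxa1 3.11-fold and Itgax 3.42-fold higher.

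Cytotoxic effector genes were higher in 16 of 17 members, with a median of 1.09 (0.73 to 1.32), and Gzmb was 1817 against 680.5 CPM, 2.67-fold higher (2.59 to 2.76). Against anti-PD1 in place of PBS the median of this list was 0.0070, so this result too rests on the PBS library. Stem-like and memory genes were higher in 12 of 14, with a median of 0.89 (0.39 to 1.37) and Tcf7 at 1.73-fold higher (1.49 to 2.02). Cell cycle genes were lower in 30 of 33 and higher in 1, with a median of -0.58 (-0.82 to -0.42), and Mki67 was 1.74-fold lower (1.61 to 1.88). The median for chemokines and their receptors was 0.51 (-0.28 to 1.44), for costimulatory receptors 0.21 (-0.16 to 0.82) and for type I interferon response genes 0.33 (0.013 to 0.72). Pdcd1 was 1.56-fold higher (1.49 to 1.63), Ifng 1.39-fold higher (1.27 to 1.51), Havcr2 1.17-fold lower (1.06 to 1.29), Il2rb 1.06-fold lower (1.03 to 1.10), although higher under median-of-ratios scaling, and Cd8a 1.03-fold lower (0.994 to 1.06). Cluster T4 held 38.0% of the cells in combination and 9.32% in PBS, and T3 29.2% and 52.3%.

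Of the combination's NK-like cells 94.6% lay in cluster T1, against 4.30% in PBS. Gzmf was 351 against 2.60 CPM, 135-fold higher (46.1 to 655), Gzmd 49.5-fold higher (28.3 to 96.0), Gzmg 298 CPM against 0 UMIs, and Ifitm1 61.2-fold higher (20.9 to 297), whereas with cells classed by their own marker UMIs its log2 ratio was -0.0046. Hspa1a, Hes1, Klf4 and Zbtb10 were lower, from 7.42-fold to 50.4-fold. The T-cell genes Cd3g and Cd8b1, chosen after their values were seen, were 199 against 19.1 and 68.4 against 5.20 CPM in the same NK-like cells. CD4 T-like cells had Ccl5, a T-cell chemokine, at 2957 against 733 CPM, 4.03-fold higher (3.57 to 4.56), Ifitm2 4.46-fold higher (3.34 to 6.07), Gzmk 9.53-fold higher (3.09 to 47.7) against 3 UMIs and Gzma 71.2-fold higher (12.6 to 2833) against 1 UMI in PBS, while Cd8b1, a CD8 T-cell gene, was 139 against 70.4 CPM in them, with lower Slc12a2, Ptprs, Top2a and Sod1, the last high in 6 classes of PBS. Treg-like cells, 201 against 217 cells, had Gzma at 559 against 41.2 CPM, 13.6-fold higher (10.1 to 18.6), Klrc1, an NK receptor gene, 23.8-fold higher (9.01 to 88.8), Gzmk 11.5-fold higher (5.83 to 25.7) and Gzmf 44.8-fold higher (7.68 to 1806). Their NK-cell receptor list had 11 of 12 members higher, with a median of 1.90 (1.29 to 2.44), and Cd8b1 was likewise higher, at 349 against 114 CPM, while Foxp3 was 1.32-fold higher (1.16 to 1.51) and Hist1h2ap, Tff1, Jdp2 and Ctsh were lower. Type I interferon response genes were lower in 20 of 22 members in macrophage-like cells, with a median of -0.80 (-1.11 to -0.51), and in 20 of 22 in monocyte-like cells, with a median of -0.87 (-1.24 to -0.55). By the fixed rule Gzmc, Hspb1, Gzma and Upp1 were higher and Slfn4, Ifit3, Fcrls and Slc15a2 lower in macrophage-like cells. Gzma lay there at 135 CPM, beside 18190.4 in NK-like cells of the library, so RNA of other cells was not excluded for granzymes in myeloid classes. In monocyte-like cells Upp1, Iigp1, Cfb and Kcna3 were higher, Iigp1 at 4.25-fold higher (3.72 to 4.88), and Retnla, Slfn4, Hspa1b and Hspa1a lower, Slfn4 at 8.05-fold lower (6.68 to 9.75). Without doublet removal the log2 ratio of Retnla was 0.058. At double the clustering resolution Gzmf, Gzmd and Gzmg in NK-like cells were 3.41-fold, 9.12-fold and 5.00-fold higher, and with cells classed by their own marker UMIs Gzmf in Treg-like cells was 2.33-fold higher.

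Fusion was compared with PBS to show the effect of the protein that joins both agents. CD8 T-like cells made up 77.7% against 17.8%, 4.36-fold higher, and 86.1% against 48.3% of T and NK cells. Treg-like cells were 12.9-fold lower and NK-like cells 2.33-fold lower as shares of all cells, although of cells other than CD8 T-like cells NK-like cells were 13.3% against 8.41% and Treg-like cells 1.32% against 4.62%. With a common minimum of UMIs the NK-like share had a log2 ratio of -0.24 (-0.53 to 0.066), but the cut drops most PBS NK-like cells. CD8 T-like cells of this library had high levels of Ifitm and granzyme genes and of cell cycle genes. Ifitm1 was 2504 against 2.74 CPM, 915-fold higher (572 to 1571), Ifitm2 1225 against 7.24 CPM, 169-fold higher (126 to 232) and Ifitm3 334 against 12.4 CPM, 26.9-fold higher (21.5 to 34.1). The granzyme genes Gzmf, Gzmg, Gzme and Gzmd were 21.8-fold higher (20.4 to 23.4), 30.5-fold higher (18.8 to 53.4), 20.2-fold higher (17.4 to 23.5) and 18.5-fold higher (16.2 to 21.2). Klra5, a receptor gene of the Ly49 family, was 63.8-fold higher (17.6 to 528) against 2 UMIs in PBS. Mrc2, which encodes a collagen receptor, Itgb8, Wnt11, Igfbp4, Tgfb3, Tff1, Dscam and Arnt2 were lower, from 29.5-fold to 389.6-fold, and Mrc2 was 0.0735 against 28.6 CPM. With doublets kept Ifitm1 was 90.8-fold, Ifitm2 9.68-fold and Ifitm3 1.20-fold higher, so the low level in PBS on which these folds rest depends on the removal of doublets.

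**Figure D3:**
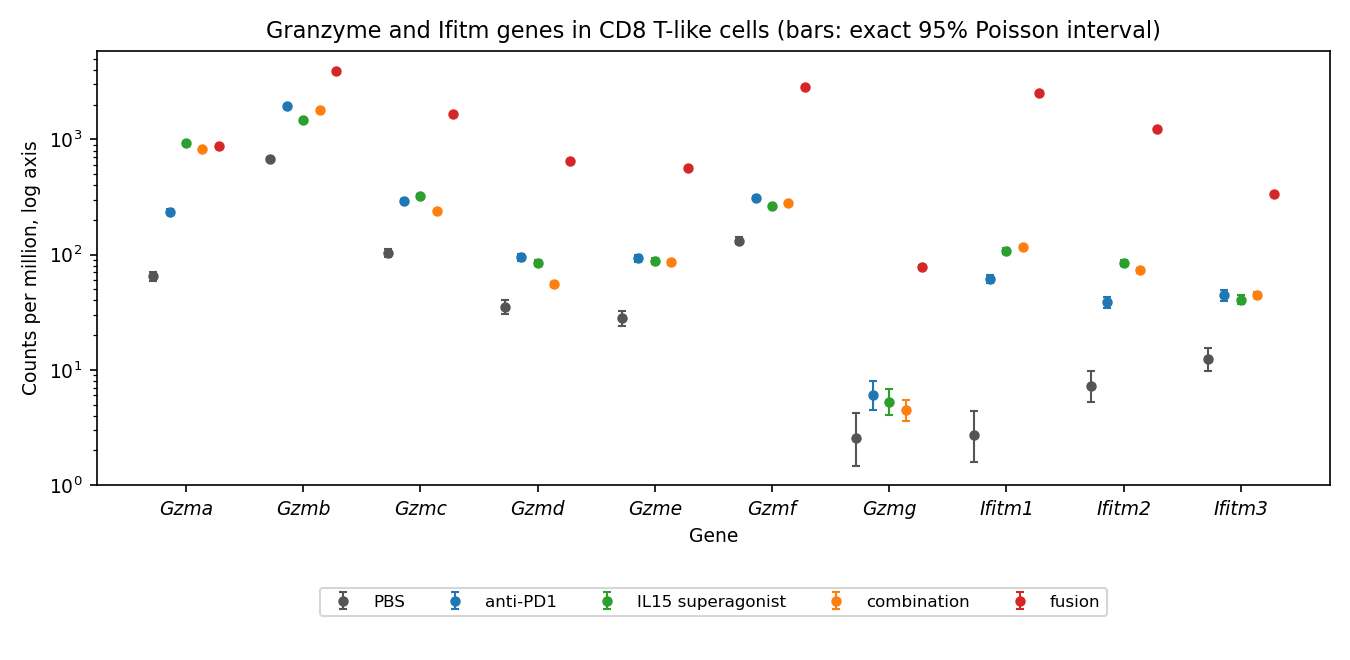
Summed level of 7 granzyme genes and 3 Ifitm genes in CD8 T-like cells in CPM on a log axis, with a point per library and exact 95% Poisson intervals as bars. Ifitm1 ranges from 2.74 CPM in PBS to 2504 in fusion and Gzmf from 132 to 2873.

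Cytotoxic effector genes were higher in 14 of 17 members and lower in 1, with a median of 1.37 (0.54 to 3.76) at percentile 100. Against combination this list split, as given below, and Gzmb is low in all 6 classes compared in PBS. Gzmc was 1653 against 104 CPM, 15.9-fold higher (14.7 to 17.2) and Gzmb 3947 against 680.5 CPM, 5.80-fold higher (5.63 to 5.98), whereas Ifng was 88.0 against 102 CPM, 1.15-fold lower (1.06 to 1.25). Cell cycle genes were higher in 26 of 33 and lower in 3, with a median of 0.65 (0.36 to 0.90). Tyms and Rrm2, enzymes that supply nucleotides for DNA synthesis, were 3.54-fold higher (3.13 to 4.00) and 3.53-fold higher (3.21 to 3.89), the mitotic cyclin gene Ccnb2 3.47-fold higher (3.10 to 3.91), and Mki67 1.38-fold higher (1.30 to 1.48). Stem-like and memory genes had 3 of 13 members higher and 9 lower, with a median of -1.36 (-2.40 to 0.45). Ccr7, a homing receptor of naive and memory cells, was 12.7-fold lower (11.6 to 14.0) and Tcf7 6.99 against 33.6 CPM, 4.82-fold lower (4.07 to 5.68), or 2.68-fold lower with a common minimum of UMIs. The chemokine list had 10 of 14 members lower and 4 higher, with a median of -0.78 (-3.22 to 0.84), and the interferon-gamma response list 12 lower and 4 higher, with a median of -0.49 (-0.84 to -0.076). The type I interferon response list, by contrast, had a median of 0.12 (-0.64 to 0.45). Inhibitory receptor and exhaustion genes had 5 higher and 12 lower around -0.33 (-1.16 to 0.13), with Pdcd1 at 852 against 378 CPM, 2.26-fold higher (2.16 to 2.35) and the transcription factor genes Prdm1, Eomes and Tox 5.88-fold lower (4.82 to 7.16), 3.90-fold lower (3.53 to 4.31) and 3.50-fold lower (3.30 to 3.71). Havcr2 was 1.21-fold lower (1.11 to 1.33), Il2rb 1.02-fold lower (0.986 to 1.05) and Cd8a 1.17-fold lower (1.13 to 1.20).

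Clusters T2, T5 and T6 held 36.8%, 29.7% and 23.2% of fusion CD8 T-like cells, against 0.196%, 0.393% and 0% in PBS, where T3 held 52.3%. Since 96.0%, 95.5% and 98.1% of the cells of T2, T5 and T6 came from the fusion library, they may be that library and not types of cell. After thinning each cell to 2000 UMIs, Mki67 was seen in 27.2% (26.1% to 28.3%) of fusion and 14.4% (12.2% to 16.8%) of PBS CD8 T-like cells, and unthinned in 54.4% and 25.5%. In anti-PD1, IL15 superagonist and combination the thinned share was 14.7%, 4.94% and 5.87%. Macrophage-like cells, which also divide, showed Mki67 in 3.03% and 3.13%. Gzmb was seen in 88.4% (87.6% to 89.2%) and 48.5% (45.3% to 51.7%) of CD8 T-like cells, and in 6.82% and 0.642% of macrophage-like cells, which should lack it. Unthinned shares of Gzmb in CD8 T-like cells were 95.3% and 63.2%. Pdcd1 was seen in 78.4% (77.4% to 79.4%) and 45.4% (42.2% to 48.7%), unthinned in 96.9% and 68.9%, and in 0.758% and 0.241% of macrophage-like cells. Median UMIs were 9126 and 4916 in CD8 T-like and 6298 and 4913 in macrophage-like cells, and thinning left out 66 shallower CD8 T-like cells in PBS, 4 in IL15 superagonist and 0 in the others. The median of all genes in CD8 T-like cells was -0.11 for fusion against PBS on the log2 scale, a small shift beside the values above.

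**Figure D4:**
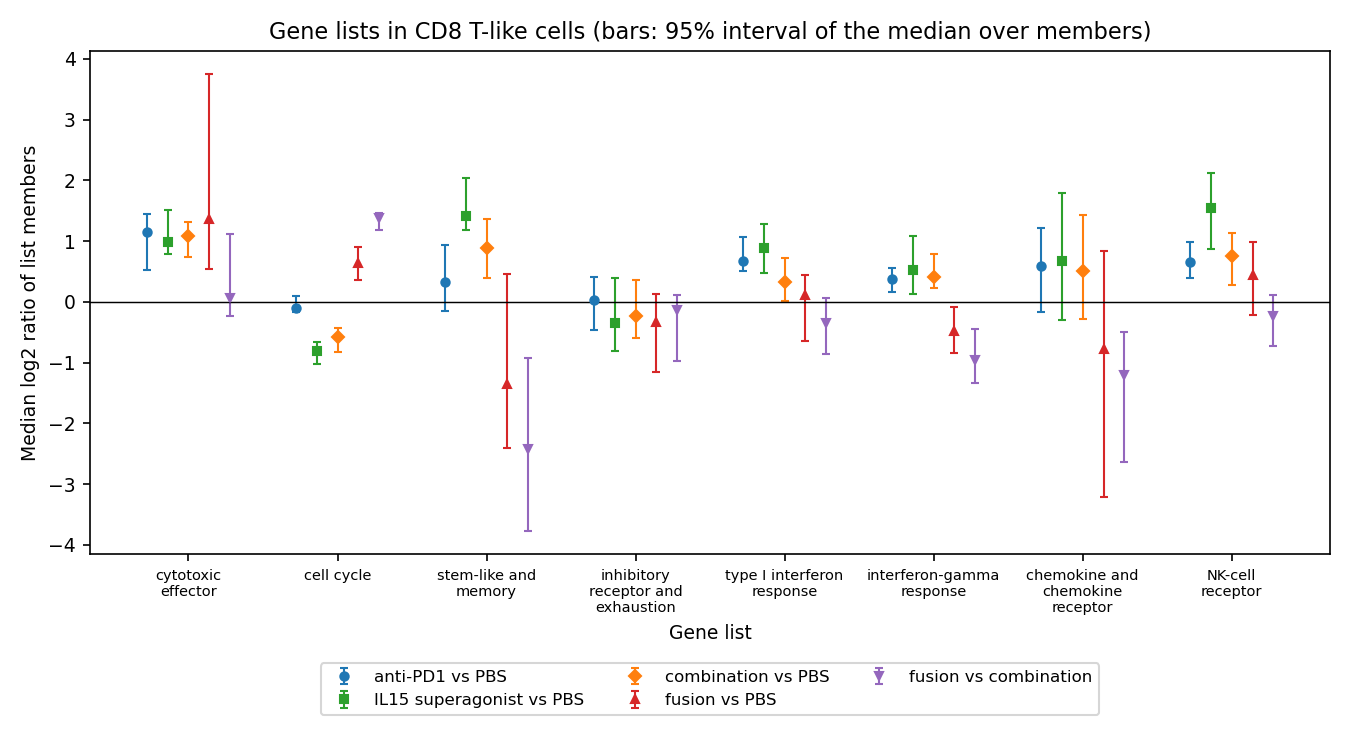
Median log2 ratio of the members of 8 gene lists in CD8 T-like cells, for 4 comparisons with PBS and for fusion against combination, with the 95% interval of the median over members as bars. The cell cycle list lies at -0.82 for IL15 superagonist and 0.65 for fusion against PBS.

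In the other classes of the fusion library cells were few, 252 NK-like, 264 macrophage-like and 444 monocyte-like cells. NK-like cells, 89.7% of them in cluster T1 against 4.30% in PBS, had Gzmf at 337 against 2.60 CPM, 129.7-fold higher (44.0 to 632), Gzmd 60.4-fold higher (34.3 to 117), Ifitm1 83.7-fold higher (28.3 to 409) and Gzmg at 758 CPM against 0 UMIs. Cd3g and Cd8b1 were 129 against 19.1 and 54.2 against 5.20 CPM in them. With cells classed by their own marker UMIs Ifitm1 was 1.65-fold higher, and at double the clustering resolution Gzmg was 3.34-fold higher. Spry2, Cxcr4, Tmem189 and Erdr1 were lower in NK-like cells, from 6.61-fold to 16.1-fold. Granzyme UMIs were also seen in myeloid classes. Monocyte-like cells had Gzmf at 120.1 against 0.177 CPM, 678-fold higher (121 to 26859.8) against 1 UMI in PBS, Gzmc at 44.9 against 0.354 CPM and Gzmd at 23.2 against 0.177 CPM, and macrophage-like cells Gzmc at 32.1 against 0.129 CPM and Gzmf at 36.3 against 0.386 CPM. Macrophage-like cells had Upp1 12.8-fold higher (9.60 to 17.2) and Serpinb2 10.5-fold higher (7.37 to 15.1), and lower Fcrls, S100a9, Cxcr4 and S1pr1, and C1qa was 1965 against 1872 CPM, lower under the stricter cell filter. Monocyte-like cells had lower Retnla, Cxcr4, Hspa1b and Wnt11, with Cxcr4, the receptor for Cxcl12, at 7.08-fold lower (6.21 to 8.11). S100a9, a neutrophil gene, was higher in monocyte-like and lower in macrophage-like cells, and its direction turned in each of them with the filter or the resolution of clustering. Type I interferon response genes were lower in 16 of 22 members in macrophage-like and 17 of 22 in monocyte-like cells, with medians of -0.48 (-0.96 to -0.27) and -0.42 (-0.999 to -0.16).

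Fusion against combination asks whether joining the parts differs from mixing them, and does not involve the PBS library. CD8 T-like cells were 77.7% against 38.4% of all cells, 2.02-fold higher, and 86.1% against 54.5% of T and NK cells. Treg-like cells were 8.36-fold and NK-like cells 4.54-fold lower, but among cells other than CD8 T-like cells they were 1.32% against 3.99% and 13.3% against 21.9%. In CD8 T-like cells all 33 cell cycle genes were higher, with a median of 1.37 (1.19 to 1.46), led by Rrm2 at 244 against 54.9 CPM, 4.44-fold higher (4.18 to 4.72), Ccnb2 at 3.67-fold higher (3.44 to 3.92), Tk1, a thymidine kinase, at 3.58-fold higher (3.33 to 3.86) and Birc5, a mitosis regulator, at 2.98-fold higher (2.86 to 3.11). With cells thinned to equal depth the cell cycle list in CD8 T cells, fusion vs combination, had a median of 2.07, and Mki67 was 223 against 92.4 CPM, 2.42-fold higher (2.30 to 2.53), or 4.98-fold at equal depth. All 14 stem-like and memory genes were lower, with a median of -2.42 (-3.78 to -0.92), among them S1pr1 13.7-fold lower (12.2 to 15.6) and Tcf7 8.34-fold lower (7.50 to 9.30). All 14 chemokine and chemokine receptor genes were lower too, with a median of -1.21 (-2.63 to -0.50), among them Cxcr4 7.85-fold lower (7.33 to 8.41), Ccl3 at 61.4 against 381 CPM, 6.20-fold lower (5.97 to 6.44) and Ccl5 at 2269.6 against 11731 CPM, 5.17-fold lower (5.14 to 5.20).

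Ifitm1 was 2504 against 116 CPM, 21.6-fold higher (20.7 to 22.5), Ifitm2 16.7-fold higher (15.9 to 17.6), Gzmf 2873 against 279.8 CPM, 10.3-fold higher (10.0 to 10.5), Gzmd 11.8-fold higher (11.1 to 12.5) and Gzmg 17.7-fold higher (14.4 to 21.9). With doublets kept Ifitm2 was 7.31-fold higher. Col27a1, a collagen gene, had 402 UMIs against 1, 123-fold higher (22.0 to 4888). Hrc and Tac4 had 0 UMIs in combination and were at least 19.7-fold higher and at least 9.93-fold higher than the level of 3 counts. Lower were Cxcr5, a follicle-homing receptor, with 1 UMI in fusion and 169-fold lower (29.1 to 6815), Ccr7 at 13.04 against 217 CPM, 16.7-fold lower (15.5 to 17.9), Mrc2, H2-Ob, Klf3, Cmah, Pde2a and Pou6f1, 16.2-fold to 37.1-fold for the last 6. The cytotoxic effector list split, 10 higher and 6 lower, around a median of 0.057 (-0.24 to 1.12), while Gzmb was 3947 against 1817 CPM, 2.17-fold higher (2.15 to 2.20) and Ifng 1.60-fold lower (1.53 to 1.67). Interferon-gamma response genes were lower in 16 of 20 members and higher in 3, with a median of -0.96 (-1.33 to -0.44) and examples in Iigp1 5.08-fold lower (3.83 to 6.76), Igtp 3.58-fold lower (3.37 to 3.80) and Gbp2 3.54-fold lower (3.26 to 3.85). Costimulatory receptor genes had 7 of 10 lower and 1 higher, with a median of -0.69 (-1.25 to 0.11) and Cd27 2.37-fold lower (2.29 to 2.46). The Treg function list had a median of -0.64 (-1.29 to 0.089) and the oxidative phosphorylation list 0.24 (0.049 to 0.42). Pdcd1 was 1.45-fold higher (1.42 to 1.48), Havcr2 1.04-fold lower (0.981 to 1.10), Il2rb 1.05-fold higher (1.03 to 1.07) and Cd8a 1.14-fold lower (1.11 to 1.16), although by the mean of per-cell fractions the log2 ratio of Cd8a was 0.00076. Clusters T2, T5 and T6 held 1.31%, 1.66% and 0.447% of combination CD8 T-like cells, against 36.8%, 29.7% and 23.2% in fusion.

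NK-like cells of both libraries lay mostly in cluster T1, 89.7% and 94.6%. The mitotic gene Ube2c was 15.0-fold higher (8.42 to 28.1), with Mt1, Nrgn and Serpine2 also higher, and Ly6c2 was 4.03-fold lower (3.38 to 4.84), with Lars2, Gpx8 and Erdr1 also lower. Ube2c, Nrgn and Serpine2 also lead CD8 T-like clusters, and RNA or doublets of those cells were not excluded. At equal depth the cell cycle list turned direction in NK-like cells. With cells classed by their own marker UMIs the log2 ratio of Ly6c2 was 0.12, and Gzmb, 1.20-fold lower (1.14 to 1.25), turned to higher there and at the lower clustering resolution. Macrophage-like cells had Ccl8, a monocyte-attracting chemokine, at 4080.3 against 1355 CPM, 3.01-fold higher (2.91 to 3.12), and Gzmf, Cd5l and Slc40a1 higher, with S100a9, Ltc4s, Fcrls and Tppp3 lower. Monocyte-like cells had Gzmf at 120.1 against 1.61 CPM and higher S100a9, Gzmc and Gzme, with lower Klra4, Dmkn, Lars2 and Timp1. The direction of S100a9 turned in both classes with the stricter cell filter and with the lower clustering resolution. Type I interferon response genes were higher in 13 of 22 members in monocyte-like cells, with a median of 0.38 (0.18 to 0.58). As a share of cells other than CD8 T-like cells, macrophage-like cells were 13.9% in fusion and 11.3% in combination.

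The combination was compared with anti-PD1 to show what the IL15 superagonist adds to the antibody. CD8 T-like cells were 38.4% against 16.5%, 2.32-fold higher, and 54.5% against 46.2% of T and NK cells. NK-like cells were 13.5% against 9.16% of all cells, but 19.1% against 25.6% of T and NK cells. CD8 T-like cells had higher Gzma and Itgax and lower cell cycle genes. Gzma was 820.0 against 236 CPM, 3.47-fold higher (3.32 to 3.64), Itgax 4.95-fold higher (3.65 to 6.87), Gzmm, another granzyme gene, 4.53-fold higher (3.07 to 6.93), and Csf2, the growth factor GM-CSF, 4.21-fold higher (2.62 to 7.14). Clec10a, Aqp3, Sprtn and Kcnj8 were also higher. Rln3, Igfbp4, H2-Eb1, H2-Aa, Wnt11, Il10, Cd74 and Tox2 were lower, with H2-Eb1 5.87-fold lower (4.89 to 7.08) and Cd74, the invariant chain of MHC class II, 40.6 against 153 CPM, 3.78-fold lower (3.46 to 4.12). With doublets kept Itgax and Clec10a were 2.09-fold and 1.77-fold higher, and H2-Eb1, H2-Aa and Cd74 2.30-fold, 2.15-fold and 2.09-fold lower. RNA of other cells was not excluded for these. All 33 cell cycle genes were lower, with a median of -0.62 (-0.69 to -0.54), and Mki67 was 1.76-fold lower (1.64 to 1.88). Stem-like and memory genes were higher in 11 of 14 and lower in 2, with a median of 0.53 (0.31 to 1.01) that was 0.26 for the stem-like and memory list in CD8 T cells, combination vs anti-PD1, at equal depth. Glycolysis genes were lower in 15 of 16 and higher in 0, with a median of -0.41 (-0.71 to -0.23). The cytotoxic effector list had a median of 0.0070 (-0.28 to 0.42), and Gzmb was 1817 against 1931 CPM, with the direction turned when doublets were kept. Ifng was 1.78-fold lower (1.68 to 1.88), Havcr2 1.46-fold lower (1.34 to 1.58) and Tcf7 1.24-fold higher (1.11 to 1.39), while Pdcd1 at 589 against 546 CPM turned direction at equal depth. Cluster T4 held 38.0% and T3 29.2% of the cells in combination, against 15.5% and 35.7% in anti-PD1.

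NK-like cells came 94.6% from T1 in combination and 77.3% from T8 in anti-PD1. Gzmf was 351 against 5.38 CPM, 65.2-fold higher (38.0 to 123), Gzmk 14.5-fold higher (10.4 to 20.96), Ifitm1 64.1-fold higher (29.3 to 175) and Gpx8 11.5-fold higher (5.69 to 26.9), and Hspa1a, Hspb1, Ret and Hspa1b were lower. Cd3g and Cd8b1 were 199 against 37.3 and 68.4 against 11.6 CPM in these cells. Their cell cycle list was lower in 19 of 24 members, with a median of -1.18 (-1.84 to -0.68), or -0.32 at double the clustering resolution. With cells classed by their own marker UMIs Ifitm1 was 1.54-fold higher. Treg-like cells had the NK receptor genes Klrd1 8.38-fold higher (5.74 to 12.7) and Klrk1 6.44-fold higher (3.74 to 11.9), with Gzmf and Camk2n1 also higher and Nrn1, Mt2, Hspa1a and H2-Ab1 lower, and Cd8b1 was 349 against 126 CPM in them. In myeloid cells type I interferon response genes were lower in 20 of 22 members in macrophage-like and 21 of 22 in monocyte-like cells, with medians of -0.84 (-1.07 to -0.46) and -0.99 (-1.31 to -0.75), while A11 held 24.3% against 43.1% of macrophage-like cells. Ifnb1 had 0 UMIs in combination macrophage-like cells against 16.0 CPM, at least 23.8-fold lower than the level of 3 counts, and was 9.34-fold lower (3.82 to 29.6) in monocyte-like cells. Retnla, Mgll, H2-M2 and Ccl24 were higher and Ppbp, Ifit2 and Ifit3 lower in macrophage-like cells, with Ccl24, an eosinophil-attracting chemokine, 4.49-fold higher (4.06 to 4.96). In monocyte-like cells Ccl24 was 6.59-fold higher (6.12 to 7.09), with Il12b, Il4i1 and Alpk2 also higher, and Cd72, Gbp2b and Ccl8 lower. Ccl8 was only 1.33-fold lower at double the clustering resolution.

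The combination was compared with the IL15 superagonist to show what the antibody adds to the cytokine. CD8 T-like cells were 38.4% against 29.7%, 1.29-fold higher, and NK-like cells 13.5% against 20.7%. CD8 T-like cells had lower stem-like and type I interferon response genes and slightly higher cell cycle genes. Hspb1, a small heat shock protein gene, was 5.09-fold higher (3.17 to 8.66) and Erdr1 80.02 against 34.9 CPM, 2.29-fold higher (2.05 to 2.57), with Epha3, Mid1, Rgs8, Trpm1, Ms4a4a and Osr2 also higher, from 2.17-fold to 5.09-fold. The Ly49 receptor genes Klra4 and Klra9 were 5.90-fold lower (4.09 to 8.68) and 6.02-fold lower (3.69 to 10.2), Ccl1 80.9 against 278 CPM, 3.43-fold lower (3.23 to 3.64), Spp1, which encodes osteopontin, 80.9 against 271 CPM, 3.35-fold lower (3.16 to 3.56), and Ncr1 3.73-fold lower (2.47 to 5.72), with Cd83, Prss2 and Slc15a2 also lower. With cells classed by their own marker UMIs Hspb1 was 1.09-fold higher and Klra4 and Klra9 both 1.47-fold lower. NK-cell receptor genes had a median of -0.87 (-1.13 to 0.039), with 5 higher and 11 lower of 21. Over members with at least 100 UMIs it was -0.070. NK-like RNA was not excluded for these. Stem-like and memory genes were lower in 11 of 14 and higher in 1, with a median of -0.57 (-0.98 to -0.37) and Tcf7 1.49-fold lower (1.37 to 1.63). Type I interferon response genes were lower in 18 of 21 and higher in 0, with a median of -0.49 (-0.99 to -0.30). Cell cycle genes were higher in 20 of 33 and lower in 0, with a median of 0.22 (0.14 to 0.26) and Mki67 1.28-fold higher (1.18 to 1.39). The alternatively activated myeloid list, measured in CD8 T-like cells, had a median of -0.78 (-1.29 to -0.17) over 11 members. Gzmb was 1.23-fold higher (1.20 to 1.25), Ifng 1.25-fold lower (1.18 to 1.32), Havcr2 1.19-fold higher (1.09 to 1.29), Il2rb 1.01-fold lower (0.987 to 1.04) and Cd8a 1.01-fold higher (0.982 to 1.04), while Pdcd1, at 589 against 571 CPM, turned direction at equal depth. Cluster T7 held 11.7% of the cells in combination and 27.0% in IL15 superagonist, and T4 38.0% and 26.0%.

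CD4 T-like cells of the combination had Penk at 576 against 25.5 CPM, 22.6-fold higher (12.5 to 45.6), Ccl1 11.9-fold higher (5.92 to 28.1), Ccl4 5.86-fold higher (2.84 to 14.0) and Dusp14 4.26-fold higher (2.78 to 6.83). Under the stricter cell filter Ccl4 was 1.34-fold higher. The type 2 cytokine genes Il5 and Il13 were 8.55-fold lower (6.44 to 11.5) and 4.92-fold lower (3.78 to 6.46) there, Csf2 3.02-fold lower (2.38 to 3.85) and Cd74 2.80-fold lower (1.97 to 4.00), and Cd4 was 1.13-fold lower (0.913 to 1.41). In NK-like cells, nearly all of cluster T1, Erdr1, Ifitm1, Cd8b1 and Pdcd1 were higher, Ifitm1 at 2.12-fold higher (1.88 to 2.40), and Ctsg, Mt1, Atp5k and Ddx43 lower, although Pdcd1 turned to lower when cells were classed by their own marker UMIs. Macrophage-like cells had lower cell cycle genes, 30 of 33 with a median of -0.88 (-1.11 to -0.72). Ifnb1 had 0 UMIs in combination against 24.3 CPM, with Penk, Pbk and Casc5 also lower and S100a9, Marco, Saa3 and Retnla higher. Monocyte-like cells had Saa3, a serum amyloid gene, at 10.7-fold higher (7.02 to 17.0), with Il4i1, Eno3 and Ifitm1 also higher and Gzmc, Cxcl3, Cd209a and Mmp12 lower.

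Lists that mark background were measured in the same cells. Housekeeping genes in CD8 T-like cells had medians of 0.30, 0.31, 0.32 and 0.51 for anti-PD1, IL15 superagonist, combination and fusion against PBS, within the range of random lists that was not called, and 0.14 for fusion against combination. Melanoma transcripts had too few UMIs in CD8 T-like cells for a median. In monocyte-like cells of anti-PD1 against PBS their median was 1.28 (0.58 to 2.81) over 4 members. Of the hemoglobin list Hbb-bs was seen at 10.2 CPM in macrophage-like cells of anti-PD1 and in no CD8 T-like cell of any library. Hemoglobin and sex-linked lists had fewer than 4 members with enough UMIs, so neither has a median. Positions in the mm10 build, from GENCODE release 21 for mouse, place the protein-coding genes Gzmb at chromosome 14, 56258838 to 56262260, Gzmc at 14, 56231441 to 56234656, Gzmd at 14, 56129556 to 56132608, Gzme at 14, 56117626 to 56120625, Gzmf at 14, 56205263 to 56211417, and Gzmg at 14, 56156582 to 56159579. Gzma lies at chromosome 13, 113093825 to 113100981. Ifitm2, Ifitm1 and Ifitm3 lie side by side on chromosome 7, at 140954837 to 140955987, 140967221 to 140969825 and 141009586 to 141010770. Mki67 lies at chromosome 7, 135689784 to 135716361, Tcf7 at chromosome 11, 52252371 to 52283014, Pdcd1 at chromosome 1, 94038305 to 94052553, Cd8a at chromosome 6, 71373427 to 71379173, and Foxp3 at chromosome X, 7573644 to 7595245.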

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

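Chosen after their result was seen were the tests on PBS and those of Ifitm genes on type I interferon and free RNA. The tests on granzymes in monocyte-like cells and on the makeup of clusters were written before.

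Beta-chain V segments, which no comparison of the report used by segment, gave a share above the upper bound of the PBS control in each treated library for the segments below, picked per library for the highest ratio of lower bound to that upper bound. The bounds cover counting of cells in single libraries only, so this is no test between treatments. Segments were assigned in 240 of 1019 CD8 T-like cells of PBS, or 23.6%, and in 683, 1312, 1870 and 3990 cells, or 59.7%, 68.0%, 59.7% and 60.5%, of anti-PD1, IL15 superagonist, combination and fusion. Trbv26 was carried by 12.0% (9.66% to 14.7%) of assigned cells in anti-PD1, against 1.67% (0.456% to 4.21%) in PBS. Trbv2 was carried by 2.90% (2.06% to 3.95%) in IL15 superagonist and 3.37% (2.60% to 4.29%) in combination, against 0 of 240 cells in PBS, where the upper bound is 1.53%, and by 4.69% (3.23% to 6.55%) in anti-PD1 and 2.63% (2.16% to 3.18%) in fusion, so PBS differs in it from every other library. Trbv20 was carried by 8.997% (8.13% to 9.93%) in fusion, against 2.5% (0.923% to 5.36%) in PBS. The most frequent segment was Trbv14 with 29.6% in PBS and Trbv19 with 22.0%, 19.4%, 21.1% and 17.8% in the others. Single expanded clones, different mice and the low recovery of V segments in PBS are not separated by these shares, and no biological explanation was tested.

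The PBS library lay apart from the others in unrelated cell classes. A response shared by all 4 treatments would leave the V and C parts of the same receptor transcript in proportion, yet the ratio in PBS was 0.194 of that of the lowest other library in CD8 T-like cells, which argues against it for the V segments. For single genes, 15 lay apart in all 6 classes in PBS, against at most 1 in the others. A shared response and a technical difference of the library cannot be told apart for these, because they were picked for lying apart and PBS is the only untreated library. What sets the V segments apart, for example read length or preparation, stays open too, since the sources used here give none. Results against PBS that rest on Aldoa could carry part of such a difference.

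Granzyme UMIs were seen in monocyte-like cells of fusion, 785 UMIs of 5 granzyme genes in 444 cells. Free RNA from CD8 T-like cells would reach cells without any T-cell UMI, and the 255 such cells carried granzymes at 0.531 (0.465 to 0.603) of the level of all monocyte-like cells, 146 against 276 CPM, on both sides of the bound of 0.5 set in advance. Remaining doublets would put most granzyme UMIs in the 5% of cells with the most T-cell UMIs, and these 23 cells held 50.7% (47.1% to 54.3%), also across the bound. The median ratio of monocyte-like to CD8 T-like level was 2.97% for granzymes and 3.02% for 8 T-cell genes. Free RNA and doublets cannot be told apart because both intervals include the bound, and expression by monocytes was not tested.

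Ifitm genes were higher in CD8 T-like cells of fusion. A general type I interferon response would raise the whole list, but its median log2 ratio was 0.12 (-0.64 to 0.45), which argues against it. Free RNA from myeloid cells would carry their proportion of Ifitm1 to Ifitm3, which was 7.50 in CD8 T-like cells against 0.527 in cDC2-like, 0.0525 in monocyte-like and 0.0556 in macrophage-like cells, 14.2 times the highest of these. Another makeup of clusters would leave no difference within clusters, where the log2 ratio of Ifitm1 to combination was 2.76 in T3, 4.75 in T4, 3.85 in T5, 4.53 in T11 and 3.60 in T14, with a median of 3.85. The size against PBS rests on the removal of doublets, since with doublets kept the log2 ratio of Ifitm1 was 6.51 and that of Ifitm3 0.26, while Ifitm1 against combination was 4.30. How reads were shared among the Ifitm genes and a difference of this single library stay open, so a rise of Ifitm genes in CD8 T cells with the fusion is a hypothesis that may not hold in other mice.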

How the results depend on the processing

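Chosen only after seeing the data were the settings with anti-PD1 as the reference, shares among cells other than CD8 T-like cells, and a common minimum of 2671 UMIs. So were the restriction of single genes to the classes where they are reported and the rule for which values count as called. Values are log2 ratios, with the value reported in square brackets. The cause of a change was not tested, except where the denominator itself makes it. No paired analysis was possible because the labels give 1 library per treatment and no test was made.

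Over 15 settings, single genes were re-computed 4658 times, of which 3896 stayed within their 95% interval, 733 moved beyond it and 29 called values turned direction. For lists it was 8302 times, with 8135, 162 and 5, and for shares 594 times, with 456, 128 and 10. Of all values in the reported set 44 of 13554 values turned, in 33 of 1315 results. Only called results could count as turned, whereas these totals hold all results, so changes of sign in other results are not counted. With each fixed gene in each class counted it was 68 of 17067, in 55 of 1698 results. A stricter minimum of 100 UMIs for list members and no such filter turned none. The directions of the cytotoxic effector, cell cycle and stem-like lists in CD8 T-like cells of fusion and combination against PBS and of the 3 Ifitm genes in fusion did not turn under any setting run on them. For IL15 superagonist the cytotoxic effector list did turn, with anti-PD1 as the reference. For combination, where this was not run, the direct median was 0.0070. Sizes were less stable. Of all values 718 in 380 results moved by more than 1.5 times, 140 of them at equal depth, 108 with cells classed by marker UMIs, 89 with a common minimum of UMIs, 78 by per-cell fractions and 77 without doublet removal. The last brought Ifitm3 in CD8 T-like cells of fusion against PBS to 0.26 [4.74].

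Shares depended on the denominator. Among T and NK cells the CD8 T-like share was -0.21 [0.73] for IL15 superagonist, 0.17 [1.10] for combination and 0.83 [2.12] for fusion against PBS, 0.66 [1.02] for fusion against combination and 0.24 [1.21] for combination against anti-PD1. In the same order the NK-like share was 0.64 [1.58], 0.032 [0.96], -2.51 [-1.22], -2.54 [-2.18] and -0.42 [0.56]. The Treg-like share was -2.63 [-1.69], -1.56 [-0.62] and -4.95 [-3.66] against PBS and -1.21 [-0.24] for combination against anti-PD1, where the CD4 T-like share was -0.22 [0.76]. The share of T0 was -0.64 [0.65] for fusion against PBS.

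Among cells other than CD8 T-like cells the NK-like share was 1.81 [1.58], 1.38 [0.96] and 0.66 [-1.22] for IL15 superagonist, combination and fusion against PBS. It was -0.72 [-2.18] for fusion against combination, 0.99 [0.56] for combination against anti-PD1 and -0.43 [-0.62] against IL15 superagonist. The Treg-like share was -0.21 [-0.62] for combination and -1.78 [-3.66] for fusion against PBS, -1.57 [-3.04] for fusion against combination and 0.20 [-0.24] for combination against anti-PD1. Turned were monocyte-like cells for combination against PBS at 0.083 [-0.33], and macrophage-like cells at 0.30 [-1.16] and T0 at 0.80 [-0.66] for fusion against combination.

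With anti-PD1 as the reference the CD8 T-like share was 2.23 [2.12] for fusion, the NK-like share 1.18 [1.58] for IL15 superagonist and -1.62 [-1.22] for fusion, and the Treg-like share -1.31 [-1.69] for IL15 superagonist. In CD8 T-like cells of IL15 superagonist the stem-like list was 1.17 [1.41] and the cytotoxic effector list -0.073 [0.99].

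With cells classed by their own marker UMIs the CD8 T-like share was 0.87 [0.73] for IL15 superagonist and 1.24 [1.10] for combination against PBS and 0.94 [1.02] for fusion against combination, and the NK-like share 0.32 [0.56] for combination against anti-PD1. The cell cycle list in CD8 T-like cells was 1.47 [1.37] for fusion against combination. Turned in NK-like cells were Ifitm1 for combination against PBS at -0.0046 [5.71], Gzmb at 0.25 [-0.26] and Ly6c2 at 0.12 [-2.01] for fusion against combination, and Gzmb at -0.073 [0.041] and Pdcd1 at -0.43 [1.09] for combination against IL15 superagonist.

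Without doublet removal the CD8 T-like share was 1.08 [1.21] for combination against anti-PD1, where Gzmb in these cells turned at 0.019 [-0.088]. Against PBS the immediate early list turned in CD8 T-like cells of IL15 superagonist at -0.078 [0.63], the cell cycle list in CD4 T-like cells of combination at 0.17 [-0.83] and Retnla in its monocyte-like cells at 0.058 [-4.28].

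A common minimum of UMIs gave an NK-like share of 1.09 [0.41], 2.57 [1.58], 1.97 [0.96] and -0.24 [-1.22] for anti-PD1, IL15 superagonist, combination and fusion against PBS and 0.88 [0.56] for combination against anti-PD1, where the B-like share turned at 0.57 [-0.71]. The cut lies above the median UMIs of PBS NK-like cells, 2408, so it drops most of them and raises the ratios to PBS. C1qa in macrophage-like cells of fusion against PBS turned at -0.35 [0.070], and S100a9 in monocyte-like cells of fusion at -2.65 [4.30] against PBS and -1.96 [4.27] against combination. With at least 500 genes and at most 5% mitochondrial UMIs these were -0.29 [0.070], -2.61 [4.30] and -2.91 [4.27], and S100a9 in macrophage-like cells was 1.21 [-5.74] against PBS and 0.64 [-6.34] against combination.

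At the lower resolution of 0.5 the NK-like share of fusion was -0.94 [-1.22] against PBS and -1.90 [-2.18] against combination, and Gzmb in NK-like cells turned at 0.36 [-0.26]. S100a9 was 1.35 [-5.74] and 0.76 [-6.34] in macrophage-like and -1.24 [4.30] and -1.34 [4.27] in monocyte-like cells. At the higher resolution of 2 the share of T0 for fusion against PBS turned at -1.39 [0.65], Hspa1a in T0 for fusion against combination at 0.044 [-2.42] and Gzmb in NK-like cells for combination against IL15 superagonist at -0.0072 [0.041]. In settings that cluster anew, T0 stands for the largest unnamed T-cell cluster, which need not hold the same cells.

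Depth and scaling moved the cell cycle list in CD8 T-like cells without turning it. With cells thinned it was -1.36 [-0.82], -1.07 [-0.58] and 0.96 [0.65] for IL15 superagonist, combination and fusion against PBS, 2.07 [1.37] for fusion against combination, and -0.99 [-0.62] and 0.32 [0.22] for combination against anti-PD1 and IL15 superagonist. As the mean of per-cell fractions it was -1.27 [-0.82], -0.98 [-0.58], 1.06 [0.65], 2.18 [1.37] and -0.98 [-0.62], in the same order without the last. Without ribosomal and mitochondrial genes in the total it was -0.18 [-0.095] for anti-PD1 against PBS. Thinned, the stem-like list was 0.26 [0.53] for combination against anti-PD1, and for fusion against combination the cell cycle list turned in NK-like cells at -0.039 [0.71] and in T0 at -0.064 [1.19]. Pdcd1 in CD8 T-like cells of combination turned thinned, at -0.037 [0.11] against anti-PD1 and -0.028 [0.045] against IL15 superagonist, and by per-cell fractions at -0.032 [0.11] against anti-PD1. Cd8a for fusion against combination turned at 0.00076 [-0.18] by per-cell fractions, and Il2rb for combination against PBS at 0.010 [-0.091] under median-of-ratios scaling. In NK-like cells of combination, without ribosomal and mitochondrial genes, Il2rb turned at -0.085 [0.16] against PBS and Gzmb at -0.032 [0.11] against anti-PD1. Depth limits Treg-like and CD4 T-like cells of fusion, with 25 and 36 cells, in which no gene was compared.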

Other observations

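Both patterns below were noticed in the data, with no further test. Cluster T0, Cd3-positive cells led by Klra6, Klra1 and Tcf7 that could not be named, followed CD8 T-like cells in part. Its Gzma level was 2699, 2871 and 3414 CPM in IL15 superagonist, combination and fusion, against 24.7 in PBS and 213 in anti-PD1, a gene chosen after its values were seen. Cytotoxic effector genes were higher in 14 of 17 members in fusion against PBS, with a median log2 ratio of 1.35 (0.77 to 2.55). NK-cell receptor genes had medians of 0.99 (0.27 to 1.68), 0.88 (0.28 to 1.85) and 1.20 (0.97 to 1.81) in IL15 superagonist, combination and fusion. Inhibitory receptor and exhaustion genes were higher in 12 of 17 members in fusion, with a median of 1.10 (0.48 to 1.73), unlike in CD8 T-like cells, where it was -0.33.

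Type I interferon response genes went opposite ways in CD8 T-like cells and in myeloid classes with the IL15 superagonist. In CD8 T-like cells their median against PBS was 0.89 (0.48 to 1.28), and in macrophage-like and monocyte-like cells -0.71 (-0.86 to -0.40) and -0.85 (-1.17 to -0.40). The combination gave 0.33 (0.013 to 0.72), -0.80 (-1.11 to -0.51) and -0.87 (-1.24 to -0.55). With anti-PD1 alone the medians were 0.68 (0.51 to 1.07) in CD8 T-like, 0.79 (0.61 to 1.01) in Treg-like, 0.032 (-0.27 to 0.27) in macrophage-like and 0.13 (-0.036 to 0.37) in monocyte-like cells. With doublets kept the median in CD8 T-like cells of IL15 superagonist was 0.26. The PBS library is shared by all of these, so a value particular to it moves them together.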
